A study of Drosophila melanogaster with 18 samples.

How the data were processed

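RNA from about 50 hand-picked Drosophila embryos per biological replicate was measured on Affymetrix arrays with 18952 probe sets. The deposited values are linear intensities made with the MAS5 algorithm, per the submitters' processing notes. The MAS5 version and its scaling target are not given in the sources used here. There are 6 groups of 3 arrays, 18 in all, and no array was left out.

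The tests, gene lists, alternatives and thresholds were chosen before the data were examined, and exceptions are named where their results appear. The scaling rule was part of that choice. The 2%-trimmed mean intensities of the arrays ran from 145.5 to 279.1, a ratio of 1.92. This passed the 10% limit of the rule, so the arrays were quantile normalised to one shared distribution and then log2 transformed. Values below the smallest positive intensity of 0.1 were set to it. The other scalings tried were the deposited scale, centring each array on its median, and centring on ribosomal protein probe sets. Centring on the spiked poly-A control probe sets was added after seeing the data.

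Of the 18769 probe sets that are not controls, 14560 were tested, those with at least 3 arrays at or above the 40th percentile of the table, an intensity of 12.0. A group was said to be below background when its arrays lay under 31.95, the 95th percentile of 20 negative control probe sets. Where the dimmer group was below background on every array, the ratio of the brighter group to the background is given as a lower bound ("at least"). Such differences have no order, whatever the size of the fitted one. Where the dimmer group was above background on some of its arrays, intensities and the number of those arrays are given. Where the mean log2 level of the brighter group was below background too, the same is given for the brighter group in place of a ratio.

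One linear model with 6 group means was fitted to all 18 arrays with limma (version 3.58.1, R 4.3.3). Contrasts were moderated with an intensity trend and adjusted by Benjamini-Hochberg over the tested probe sets. A probe set was called at an adjusted p below 0.05. The word adjusted refers to this procedure for single genes. Errors of log2 differences are standard errors from the model and errors of intensities are SDs over n = 3 arrays. All printed intensities are quantile normalised unless said otherwise.

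Gene symbols came from the array annotation, which gave a single gene for 13647 probe sets, several for 402 and none for 4720. Gene-level statements used the brightest probe set of each of 10035 tested genes. Genome coordinates were not used here, only the chromosome arm. The panel genes stg, w and roX1 had no probe set with a single symbol, so they were not analysed here.

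There were 23 gene lists: gap and terminal, pair-rule, segment polarity and Hox, dorsoventral patterning, cellularization and gastrulation, early zygotic genes of the syncytial cycles, Bearded and Enhancer of split family, DNA replication, cell cycle regulators, maternal transcripts cleared at the transition, maternal-zygotic transcription regulators, histone, ribosomal protein, heat shock, DNA damage and cell death, germ cell, amnioserosa and yolk nuclei, sex determination and dosage compensation, immune response, mother tissue, and later embryo markers of nervous system, of muscle and blood, and of epidermis and cuticle. Each list was tested in 10 contrasts with limma camera at a preset correlation of 0.01, adjusted over all lists and contrasts. The alternative estimated the correlation from the data. Medians of lists are log2 differences relative to the median of all tested genes.

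Genes changed at least 2-fold between diploid cycle 13 and early cycle 14 were sorted by their haploid cycle 14 level. The same adjusted tests against each diploid stage were used. The position, haploid minus cycle 13 level over the diploid change, is 0 at the cycle 13 level and 1 at early cycle 14. A simulation with 200 changed probe sets recovered 35.5% at 2-fold and 59.0% at 4-fold. So few changes tighten its cutoff. Rises set to the cycle 13 level were sorted there in 93.1%, falls set to early cycle 14 in 96.4%, of those selected again. This is optimistic, as 5.3% and 2.7% had no class against 25% of real ones.

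Named genes follow a fixed rule. For each comparison of 2 groups they are the 10 called genes with the largest rise and the 10 with the largest fall whose arrays do not overlap between groups and whose brighter mean reached the 60th percentile, an intensity of 28.95. Members of the lists, a fixed panel of regulators, the 8 genes with the largest diploid change in each sorted class, and the largest differences between the steps of haploids and diploids were added by the same rule.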

Results

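Transcript levels were measured in whole embryos with a normal diploid genome and in haploid embryos laid by maternal haploid mothers. The embryos carried a histone GFP fusion, so that divisions could be watched and each collection timed from the telophase of a counted nuclear cycle. Diploid embryos were taken 15 min after the division of cycle 12 (cycle 13), 15 min after the division of cycle 13 (early cycle 14) and 40 min after the same division (late cycle 14). Haploid embryos were taken 15 min after the division of cycle 13 (cycle 14), and 15 min and 40 min after the division of cycle 14 (early and late cycle 15). A haploid embryo has 1 genome copy in place of 2 per nucleus and passes 1 more division before it cellularizes, so each haploid stage matches the diploid stage 1 cycle earlier in its nuclear to cytoplasmic ratio. Each of the 6 groups had 3 biological replicates. Ploidy is taken from the sample labels and has no check in these data, since the probe set for the maternal haploid gene mh stayed near background, at 42.2 ± 4.61, 23.4 ± 6.71 and 41.6 ± 3.63 in the diploid and 17.6 ± 17.3, 10.6 ± 6.19 and 51.8 ± 12.8 in the haploid stages (SD, n = 3). The design asks whether zygotic transcription and the clearance of maternal transcripts follow this ratio or follow time and cycle number.

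The arrays differed in brightness as deposited. The upper quartile of intensity averaged 236.3 in diploid cycle 13, 195.2 in diploid early cycle 14, 132.8 in diploid late cycle 14, 97.6 in haploid cycle 14, 109 in haploid early cycle 15 and 122 in haploid late cycle 15. The share of probe sets above background was lowest in haploid cycle 14 embryos at 33.4% and highest in diploid early cycle 14 embryos at 41.1%. The GAPDH control probe set for the 3' end averaged 965.2 in diploid cycle 13 against at most 151.6 in the other groups. This goes with each comparison using diploid cycle 13. The control probe set for the middle of 18S ribosomal RNA averaged 986.6 in haploid late cycle 15 against at most 395.7 elsewhere, and the same applies to comparisons using that group. After scaling, replicate arrays correlated at 0.966 to 0.982.

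Over 8486 probe sets reaching background on at least 3 arrays, haploid cycle 14 embryos were nearest to diploid early cycle 14 (r = 0.967). Same age here means the same minutes into one cycle. At the same ratio, diploid cycle 13, r was 0.924. Haploid early cycle 15 embryos lay between diploid late cycle 14 (r = 0.956) and diploid early cycle 14 (r = 0.947). Haploid late cycle 15 was nearest to diploid late cycle 14 (r = 0.959). These correlations of group means were not tested.

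The first comparison asked what changes over the last syncytial division in diploid embryos, from cycle 13 to early cycle 14. The Kruppel gap gene Kr climbed from 379 ± 27.0 to 1380 ± 104 (SD, n = 3, log2 1.87 ± 0.07, adjusted p = 2.4e-15), and slam, which builds the cellularization furrow, from 2523 ± 344 to 5504 ± 369 (log2 1.13 ± 0.10, adjusted p = 2.0e-09). Of 15 measured gap and terminal genes, 12 rose and 1 fell (12 and 1 adjusted over the list alone, median 1.32, camera adjusted p = 5.4e-08). Among them were hkb (log2 1.99 ± 0.11), kni (log2 2.22 ± 0.12) and tll (log2 1.16 ± 0.11). Of 17 dorsoventral genes, 12 rose and 0 fell (13 and 0 adjusted over the list alone, median 1.17, camera adjusted p = 5.4e-07). These included the mesoderm regulators sna (log2 1.27 ± 0.10) and twi (log2 1.81 ± 0.13) and the amnioserosa regulator zen (log2 1.33 ± 0.08).

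Among genes above background on every array of both groups, the largest rises were those of the tracheal regulator rib (log2 3.44 ± 0.12) and link (log2 3.41 ± 0.08). The naming rule takes fitted differences, so it also gave genes below background on some or all arrays of diploid cycle 13, whose rises have no order. They included the POU factor nub (at least 3.40-fold, adjusted p = 1.5e-16), kmr (at least 2.34-fold), the zinc finger factor salm (at least 1.65-fold) and the kinase subunit Pka-C3 (at least 2.94-fold). With them came the patched-related Ptr (intensity 526 ± 36.7 against 40.98 ± 17.5, 2 of 3 lower arrays above background), the helix-loop-helix factor net (at least 1.52-fold), the xanthine dehydrogenase gene ry (at least 1.07-fold) and CG43394 (at least 2.95-fold). The early zygotic list had 28 measured members, of which 21 rose and 3 fell (21 and 4 adjusted over the list alone, median 0.82, camera adjusted p = 5.1e-10, adjusted p = 0.06 with an estimated correlation). The mitotic inhibitor Z600 (log2 2.12 ± 0.09), which holds nuclei out of mitosis in cycle 14, and trbl (log2 1.95 ± 0.12), which degrades the String phosphatase, both rose. The early activator zld (log2 0.86 ± 0.13) rose as well. Of 7 pair-rule genes, 6 rose and 0 fell (6 and 0 adjusted over the list alone, median 1.00, camera adjusted p = 3.5e-04, adjusted p = 0.11 with an estimated correlation). Of 11 cellularization genes, 8 rose and 2 fell (8 and 2 adjusted over the list alone, median 0.75, camera adjusted p = 0.0011, adjusted p = 0.12 with an estimated correlation). Among 12 amnioserosa and yolk markers, 8 rose and 0 fell (8 and 0 adjusted over the list alone, median 1.07, camera adjusted p = 5.1e-04, adjusted p = 0.12 with an estimated correlation). Of 16 sex determination genes, 10 rose and 1 fell (11 and 2 adjusted over the list alone, median 0.51, camera adjusted p = 7.4e-04), with rises of Sxl (log2 2.00 ± 0.16) and msl-2 (intensity 108 ± 8.76 against 31.2 ± 5.08, 2 of 3 lower arrays above background).

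Other genes fell. Of the genes above background on every array, the glycerol kinase gene Gk2 (log2 -3.20 ± 0.24, adjusted p = 3.1e-10) and Rab23 (log2 -3.01 ± 0.19) fell furthest. Genes that fell to below background on some or all arrays, in no order, were Opbp (at least 2.11-fold), CG8323 (at least 1.93-fold), the transcription factor gene CrebB (at least 1.03-fold) and E(spl)m5-HLH (at least 1.27-fold). Further ones were MTPAP (at least 1.00-fold), syd (at least 1.84-fold), Naxe (intensity 4.08 ± 1.51 against 32.2 ± 13.8, 2 of 3 higher arrays above background) and WRNexo (intensity 36.9 ± 12.3 against 274 ± 74.5, 2 of 3 lower arrays above background). Of 22 replication genes, 2 rose and 13 fell (2 and 14 adjusted over the list alone, median -0.83, camera adjusted p = 1.9e-06). The single-strand binding protein gene RPA1 dropped from 1259 ± 163 to 199 ± 34.8 (log2 -2.67 ± 0.18, adjusted p = 5.1e-11). Of 19 maternal transcripts known to be cleared, 2 rose and 8 fell (2 and 8 adjusted over the list alone, median -0.32, camera adjusted p = 4.2e-04, adjusted p = 0.13 with an estimated correlation). The posterior determinant osk (log2 -2.12 ± 0.19) was among those that fell. Heat shock transcripts were lower, with 0 higher and 5 lower (0 and 5 adjusted over the list alone, median -1.19, camera adjusted p = 1.3e-04) of 8. The small heat shock gene Hsp26 (log2 -1.98 ± 0.11) was among them. Of 12 germ cell markers, 0 rose and 7 fell (1 and 7 adjusted over the list alone, median -0.60, camera adjusted p = 3.3e-04, adjusted p = 0.11 with an estimated correlation). The germline factor ovo (log2 -2.27 ± 0.17) was among them. The checkpoint kinase genes grp (log2 -0.98 ± 0.08), which slows the last syncytial cycles, and lok (log2 -2.07 ± 0.10) also fell.

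In this step 3977 of 14560 probe sets were called, 2443 higher and 1534 lower. With at least 2-fold change the counts were 452 and 737. The share of calls that were higher depended on scaling. It was 61.4% in the main analysis, 66.0% on the deposited scale, 43.7% with median centring, 22.97% with ribosomal protein centring and 26.8% with poly-A centring. The genes named here kept their direction under each of these scalings.

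**Figure D1:**
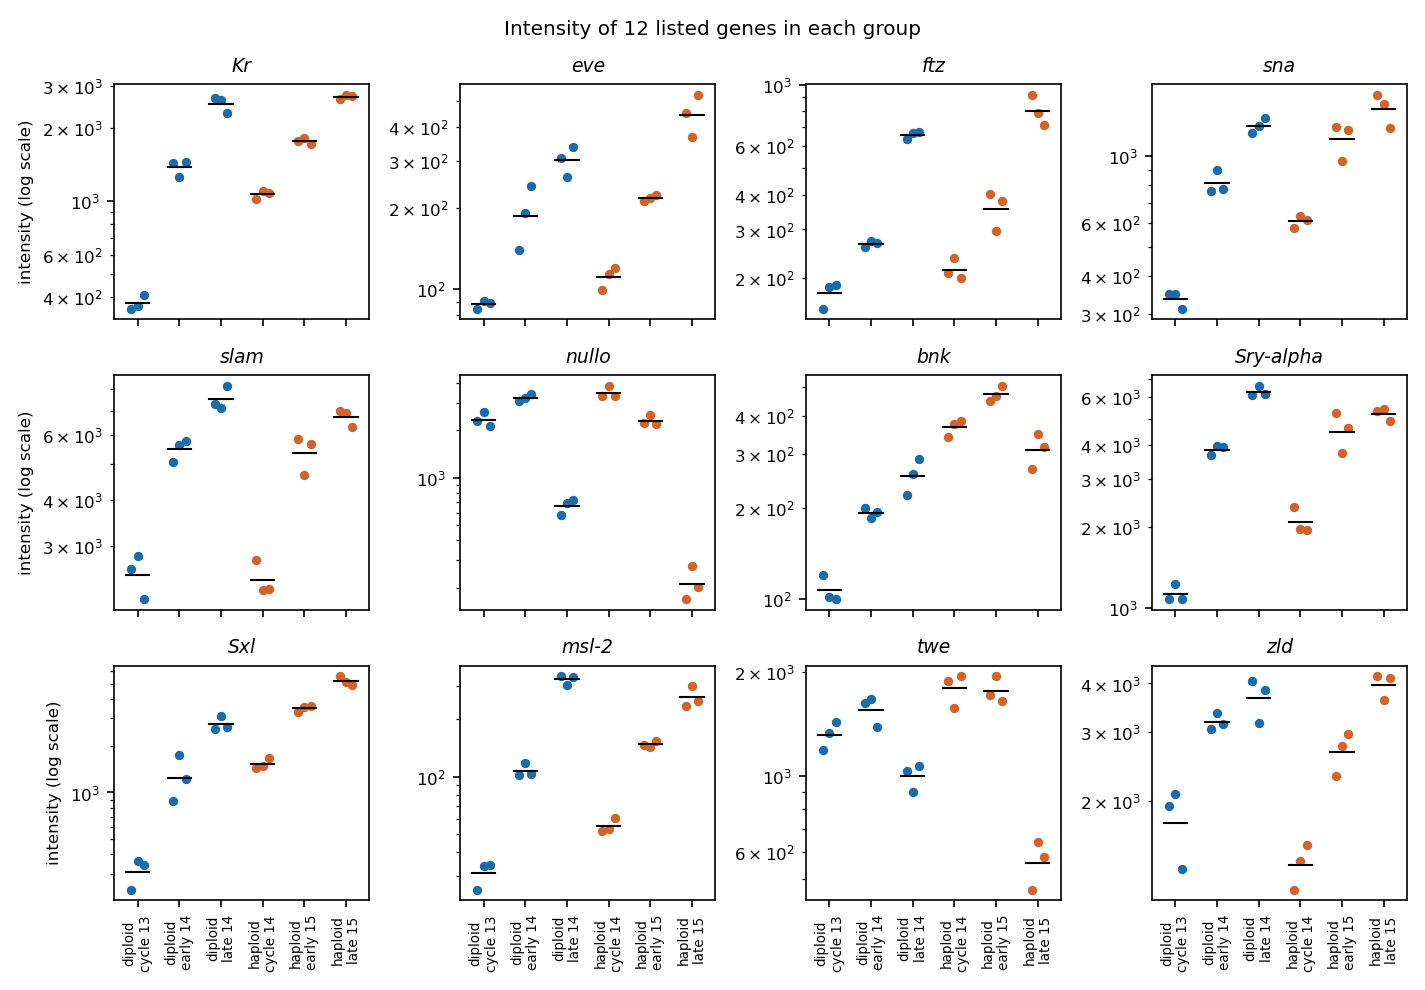
Quantile normalised intensities of named panel genes in the 6 groups, with the 3 replicates of each group drawn as points.

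The second comparison followed diploid embryos within 1 interphase, from 15 to 40 min of cycle 14. Measured above background throughout, the largest increases were those of the Hedgehog effector ci (log2 4.27 ± 0.23) and salm (log2 3.79 ± 0.42). From below background on some or all arrays, in no order, rose knrl (at least 2.76-fold), the pair-rule regulator opa (at least 23.3-fold, adjusted p = 3.2e-07), the fibroblast growth factor pyr (at least 1.19-fold) and fj (at least 1.71-fold). The same was seen for mRpL46 (at least 2.29-fold), CG1233 (at least 2.67-fold), the axon guidance gene comm (intensity 459 ± 25.9 against 31.0 ± 5.93, 1 of 3 lower arrays above background) and dan (at least 8.88-fold). Of the 7 pair-rule genes, 7 rose and 0 fell (7 and 0 adjusted over the list alone, median 1.76, camera adjusted p = 1.3e-06). Eve transcripts rose from 191 ± 50.8 to 303 ± 38.4 and ftz transcripts from 266 ± 6.17 to 660 ± 21.4 (SD, n = 3). Of the gap and terminal genes, 10 rose and 2 fell (11 and 2 adjusted over the list alone, median 0.61, camera adjusted p = 6.6e-04, adjusted p = 0.13 with an estimated correlation). Of the dorsoventral genes, 12 rose and 3 fell (12 and 4 adjusted over the list alone, median 1.16, camera adjusted p = 0.0027, adjusted p = 0.16 with an estimated correlation). Of 12 Bearded and Enhancer of split family members, 6 rose and 2 fell (6 and 2 adjusted over the list alone, median 0.53, camera adjusted p = 0.012, adjusted p = 0.34 with an estimated correlation). The blood and fat body regulator srp (log2 3.18 ± 0.16) rose in the amnioserosa and yolk list.

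The largest fall in the second step measured above background was that of Tsp66E (log2 -3.79 ± 0.15). Falling to below background, in no order, were CG14435 (at least 2.98-fold), CG34195 (at least 1.73-fold) and the arylalkylamine acetyltransferase gene AgmNAT (at least 1.01-fold). Besides these there were the one-carbon enzyme gene Shmt (at least 1.83-fold), Epac (at least 1.31-fold) and Drep2 (at least 1.57-fold). Also in this set were Rfx (at least 1.26-fold), Mct1 (at least 1.06-fold) and CenG1A (at least 6.84-fold). Maternal transcripts counted 0 higher and 14 lower (0 and 14 adjusted over the list alone, median -0.67, camera adjusted p = 1.2e-08) of 19. The anterior determinant bcd (log2 -3.17 ± 0.20, adjusted p = 7.6e-12), osk (log2 -2.502 ± 0.19) and the clearance regulator smg (log2 -1.84 ± 0.09) all fell. The mitotic genes CycB (log2 -0.97 ± 0.06) and twe (log2 -0.64 ± 0.11) fell, and the embryonic linker histone BigH1 (log2 -1.58 ± 0.10) fell as well. The cellularization gene nullo (log2 -2.29 ± 0.12) dropped. Germ cell markers numbered 1 higher and 6 lower (2 and 6 adjusted over the list alone, median -0.42, camera adjusted p = 0.011, adjusted p = 0.22 with an estimated correlation) of 12. There were 4082 calls, 2146 higher and 1936 lower, and 753 and 880 with at least 2-fold change. Calls were higher in 52.6% of cases in the main analysis, 19.7% on the deposited scale, 24.3% with median centring, 29.3% with ribosomal protein centring and 12.5% with poly-A centring.

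The third comparison asked whether haploids pass the same change at the matched ratio, from cycle 14 to early cycle 15. All 10 genes with the largest fitted rises were below background on some or all arrays of haploid cycle 14, so they have no order. They were CG7884 (at least 1.52-fold), salm (at least 3.09-fold), rau (at least 2.48-fold) and Mob2 (at least 2.32-fold). Beside them stood HLH54F (intensity 31.3 ± 7.67 against 2.09 ± 0.578, 1 of 3 higher arrays above background), kmr (intensity 194 ± 37.7 against 21.2 ± 22.7, 1 of 3 lower arrays above background) and ci (at least 6.66-fold). To these are added the fibroblast growth factor receptor htl (at least 1.01-fold), opa (at least 1.79-fold) and Dscam1 (at least 1.20-fold). Of the gap and terminal genes, 12 rose and 0 fell (12 and 0 adjusted over the list alone, median 1.10, camera adjusted p = 7.7e-10). Kr rose from 1064 ± 42.2 to 1774 ± 50.0 (log2 0.74 ± 0.07) and slam from 2434 ± 265 to 5407 ± 638 (log2 1.15 ± 0.10). All 7 pair-rule genes were called, 7 up and 0 down (7 and 0 adjusted over the list alone, median 1.247, camera adjusted p = 7.1e-07). Of the dorsoventral genes, 12 rose and 1 fell (12 and 2 adjusted over the list alone, median 1.04, camera adjusted p = 5.0e-06, adjusted p = 0.06 with an estimated correlation). Of the cellularization genes, 8 rose and 2 fell (8 and 2 adjusted over the list alone, median 0.64, camera adjusted p = 0.0026, adjusted p = 0.13 with an estimated correlation). Of the early zygotic list, 17 rose and 7 fell (17 and 7 adjusted over the list alone, median 0.49, camera adjusted p = 2.3e-04, adjusted p = 0.22 with an estimated correlation). Amnioserosa and yolk markers counted 8 higher and 1 lower (8 and 1 adjusted over the list alone, median 0.98, camera adjusted p = 0.0013, adjusted p = 0.14 with an estimated correlation) of 12.

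The 10 largest fitted falls in the haploid first step likewise ended below background on some or all arrays. In no order, they were those of the glucuronyltransferase gene GlcAT-P (at least 4.42-fold), CG17568 (at least 2.15-fold), the glutathione synthesis gene Gclc (at least 2.73-fold) and CG13005 (at least 1.16-fold). Others among them were LysS (at least 1.46-fold), C1GalTA (at least 4.12-fold) and CG5805 (at least 1.249-fold). The rest were CG34195 (intensity 22.6 ± 11.5 against 131 ± 17.9, 1 of 3 lower arrays above background), CG32485 (intensity 6.72 ± 6.25 against 32.4 ± 7.73, 1 of 3 higher arrays above background) and E23 (intensity 24.4 ± 12.9 against 132 ± 32.5, 1 of 3 lower arrays above background). Replication genes were 3 higher and 11 lower (4 and 12 adjusted over the list alone, median -0.47, camera adjusted p = 0.0056, adjusted p = 0.12 with an estimated correlation) of 22. Maternal transcripts counted 2 higher and 9 lower (2 and 10 adjusted over the list alone, median -0.41, camera adjusted p = 0.0012, adjusted p = 0.17 with an estimated correlation) of 19. Of the Bearded and Enhancer of split family, 1 rose and 3 fell (1 and 4 adjusted over the list alone, median -0.81, camera adjusted p = 0.046, adjusted p = 0.43 with an estimated correlation). Brd fell furthest of them (log2 -2.13 ± 0.12). Of 17 regulators of the maternal to zygotic change, 11 rose and 3 fell (11 and 3 adjusted over the list alone, median 0.28, camera adjusted p = 0.0046, adjusted p = 0.23 with an estimated correlation). Germ cell markers counted 1 higher and 5 lower (1 and 5 adjusted over the list alone, median -0.24, camera adjusted p = 0.02, adjusted p = 0.25 with an estimated correlation) of 12. Heat shock genes counted 1 higher and 3 lower (1 and 3 adjusted over the list alone, median -0.35, camera adjusted p = 0.048, adjusted p = 0.17 with an estimated correlation) of 8. Sex determination genes counted 8 higher and 3 lower (9 and 3 adjusted over the list alone, median 0.43, camera adjusted p = 0.04, adjusted p = 0.12 with an estimated correlation) of 16. The calls numbered 2954, 1517 higher and 1437 lower, or 502 and 453 with at least 2-fold change. Of these calls 51.4% were higher in the main analysis, 81.7% on the deposited scale, 30.1% with median centring, 46.5% with ribosomal protein centring and 93.7% with poly-A centring.

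The fourth comparison covered 15 to 40 min of haploid cycle 15, where the later group is the one with the high 18S control. The largest rises measured above background on every array were those of opa (log2 4.91 ± 0.59, adjusted p = 2.9e-07) and dan (log2 4.08 ± 0.46). Rises from below background, in no order, were those of the sulfate transporter Esp (at least 1.91-fold), knrl (at least 5.70-fold), mRpL46 (at least 4.72-fold) and the tumor necrosis factor receptor wgn (at least 1.41-fold). A rise was also called for pyr (at least 1.53-fold), CG10307 (at least 2.05-fold), Cf2 (at least 1.57-fold) and Rilpl (intensity 32.1 ± 6.90 against 2.31 ± 1.04, 1 of 3 higher arrays above background). Of the falls measured above background, those of bcd (log2 -3.92 ± 0.20, adjusted p = 1.7e-13) and CG18269 (log2 -3.63 ± 0.12) were largest. Falls to below background on some or all arrays, in no order, were those of Prestin (at least 2.07-fold), Flad1 (at least 3.73-fold), CG5567 (at least 4.19-fold) and CG13907 (at least 1.67-fold). A fall was also called for Sik3 (at least 3.62-fold), CG14435 (at least 2.53-fold), CG13716 (intensity 31.7 ± 4.63 against 375 ± 54.7, 1 of 3 lower arrays above background) and CG32365 (at least 7.24-fold). Of the pair-rule genes, 7 rose and 0 fell (7 and 0 adjusted over the list alone, median 1.51, camera adjusted p = 1.4e-06). Of the gap and terminal genes, 9 rose and 2 fell (9 and 2 adjusted over the list alone, median 0.56, camera adjusted p = 0.0092, adjusted p = 0.24 with an estimated correlation). Of the maternal transcripts, 0 rose and 15 fell (0 and 17 adjusted over the list alone, median -1.07, camera adjusted p = 5.1e-10), with twe (log2 -1.66 ± 0.11) among the mitotic genes that fell. The cellularization gene nullo (log2 -3.44 ± 0.12) fell. There were 4209 calls, 2053 higher and 2156 lower, and 1056 and 875 with at least 2-fold change. Calls were higher in 48.8% of cases in the main analysis, 45.8% on the deposited scale, 38.1% with median centring, 50.8% with ribosomal protein centring and 10.4% with poly-A centring.

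Many of the same probe sets changed at matched steps. Of the 452 that rose at least 2-fold in the diploid first step, 209 were among the 502 that rose in the haploid first step, where independence would give 15.6. Among falls the overlap was 202 of 737 and 453, where independence would give 22.9. In the second step the overlap was 492 of 753 and 1056 for rises and 383 of 880 and 875 for falls, against 54.6 and 52.9. These overlaps were counted after the steps had been seen.

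**Figure D2:**
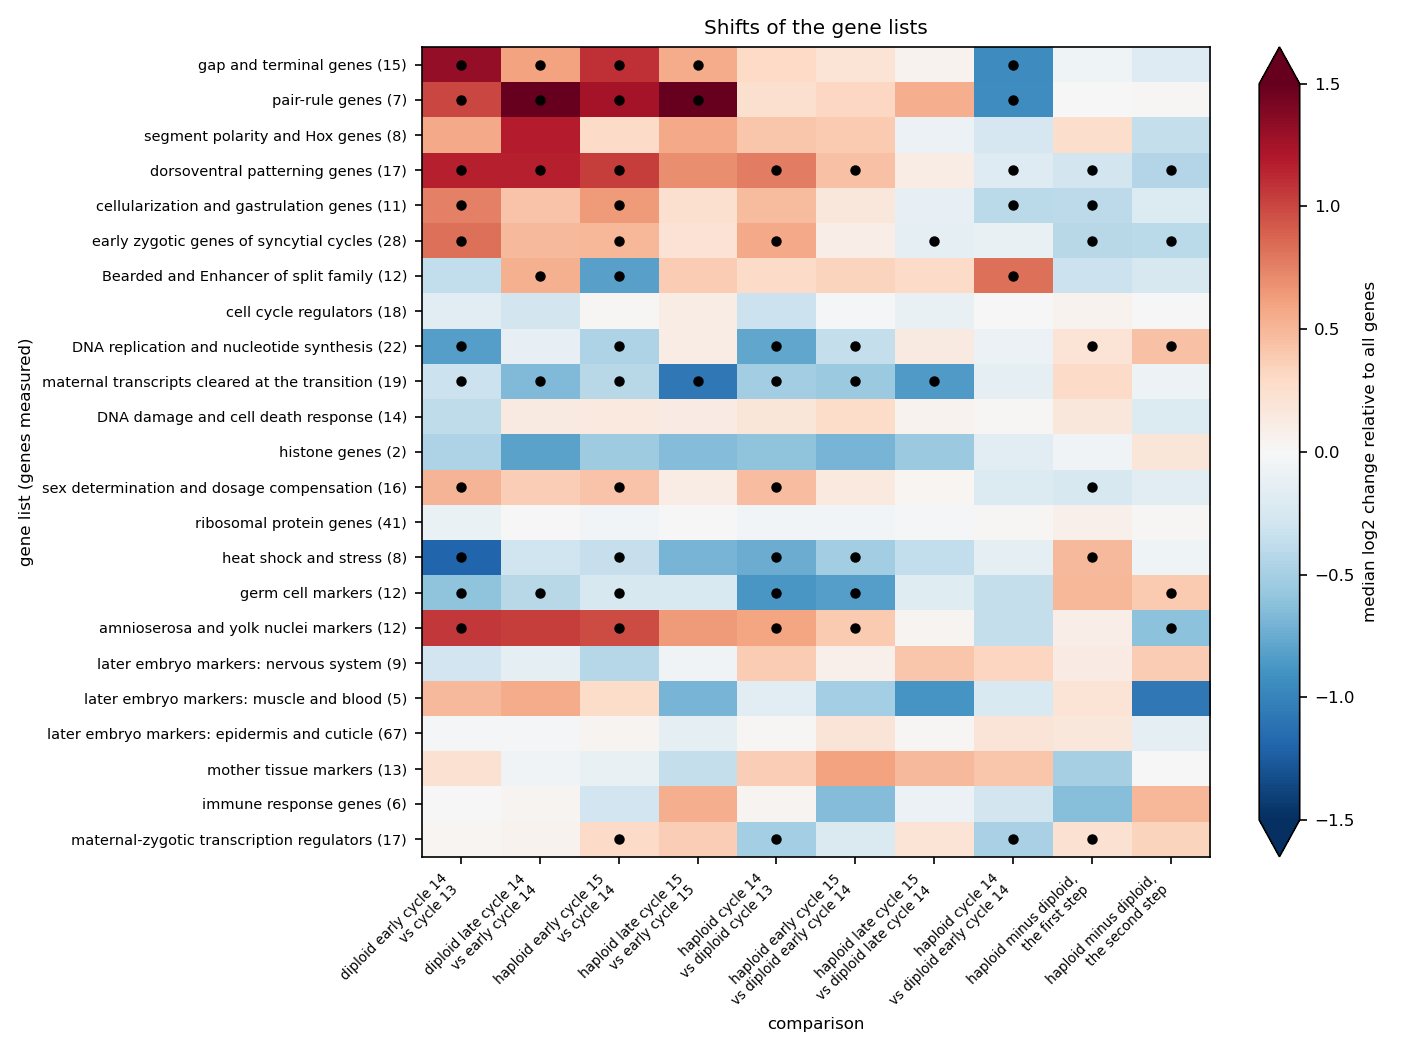
Median log2 difference of each gene list relative to all tested genes in the 10 contrasts.

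The matched-ratio comparisons asked how far haploids differ from diploids 1 cycle younger. The first stage set haploid cycle 14 against diploid cycle 13. Kr stood at 1064 ± 42.2 against 379 ± 27.0 (log2 1.49 ± 0.07, adjusted p = 9.5e-14), whereas slam stood at 2434 ± 265 against 2523 ± 344 and was not called. Of the genes above background on every array, those highest in haploids against diploids were the maternal gamma tubulin gene gammaTub37C (log2 3.73 ± 0.13, adjusted p = 6.8e-16), CG43085 (log2 3.07 ± 0.11) and the Dpp target Dtg (log2 3.02 ± 0.10). Higher in haploids and below background in diploid cycle 13 on some or all arrays, in no order, were nub (at least 1.37-fold), the cytochrome P450 gene Cyp28a5 (at least 1.61-fold), net (at least 2.34-fold) and Pka-C3 (at least 2.02-fold). So were phu (at least 6.34-fold), CG43064 (at least 3.41-fold) and CG8654 (intensity 351 ± 40.5 against 38.5 ± 8.55, 2 of 3 lower arrays above background). All 10 genes with the largest fitted difference the other way were below background in haploids, in no order. These were CG12643 (at least 24.1-fold), the immune receptor gene GNBP3 (at least 2.45-fold), MTPAP (at least 1.00-fold) and the DNA repair gene nbs (at least 3.74-fold). With them stood Shmt (at least 5.23-fold), the zinc transporter gene Zip102B (at least 1.01-fold) and CG4476 (at least 3.60-fold). Also lower were CG30159 (at least 5.49-fold), WRNexo (at least 8.39-fold) and Tbca (at least 3.06-fold).

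By lists at this stage, early zygotic genes counted 20 higher and 1 lower (20 and 2 adjusted over the list alone, median 0.57, camera adjusted p = 1.9e-06, adjusted p = 0.12 with an estimated correlation) of 28. Dorsoventral genes counted 10 higher and 0 lower (10 and 1 adjusted over the list alone, median 0.77, camera adjusted p = 0.0012, adjusted p = 0.13 with an estimated correlation) of 17. The gap and terminal list did not pass, with 6 higher and 1 lower (6 and 1 adjusted over the list alone, median 0.30, camera adjusted p = 0.096) of 15. Replication genes counted 5 higher and 14 lower (6 and 15 adjusted over the list alone, median -0.78, camera adjusted p = 9.6e-04, adjusted p = 0.09 with an estimated correlation) of 22. RPA1 stood at 115 ± 21.5 against 1259 ± 163. Maternal transcripts counted 3 higher and 12 lower (3 and 12 adjusted over the list alone, median -0.52, camera adjusted p = 1.6e-04, adjusted p = 0.12 with an estimated correlation) of 19. Germ cell markers counted 2 higher and 9 lower (2 and 9 adjusted over the list alone, median -0.88, camera adjusted p = 3.3e-04, adjusted p = 0.11 with an estimated correlation) of 12. Heat shock genes counted 0 higher and 5 lower (0 and 5 adjusted over the list alone, median -0.74, camera adjusted p = 0.0024, adjusted p = 0.067 with an estimated correlation) of 8. Sex determination genes counted 11 higher and 0 lower (11 and 0 adjusted over the list alone, median 0.46, camera adjusted p = 0.0078, adjusted p = 0.068 with an estimated correlation) of 16. Amnioserosa markers counted 7 higher and 0 lower (7 and 0 adjusted over the list alone, median 0.60, camera adjusted p = 0.019, adjusted p = 0.27 with an estimated correlation) of 12. The transcription regulators counted 4 higher and 11 lower (4 and 11 adjusted over the list alone, median -0.50, camera adjusted p = 0.0092, adjusted p = 0.27 with an estimated correlation) of 17. The checkpoint kinase gene grp (log2 -1.42 ± 0.08) was lower. In total 5192 probe sets were called, 3004 higher and 2188 lower in haploids, or 767 and 1247 with at least 2-fold difference. Haploids were higher in 57.9% of calls in the main analysis, 5.93% on the deposited scale, 51.01% with median centring, 14.4% with ribosomal protein centring and 4.61% with poly-A centring.

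At the second matched stage, haploid early cycle 15 against diploid early cycle 14, the largest differences measured above background on every array, higher in haploids, were those of gammaTub37C (log2 3.96 ± 0.13, adjusted p = 1.2e-15) and CG8654 (log2 2.93 ± 0.13). Higher in haploids from a diploid level below background on some or all arrays, in no order, were Cyp28a5 (at least 3.504-fold), the ecdysone synthesis gene sro (at least 3.00-fold), HLH54F (intensity 31.3 ± 7.67 against 3.21 ± 0.830, 1 of 3 higher arrays above background) and CG30460 (at least 3.58-fold). Likewise higher were Ugt50B3 (at least 1.72-fold), CG13217 (at least 2.59-fold), CG7884 (at least 1.52-fold) and the neuronal RNA-binding gene elav (intensity 166 ± 19.5 against 28 ± 6.58, 1 of 3 lower arrays above background). The largest difference the other way measured above background was that of the calcineurin gene Pp2B-14D (log2 -4.18 ± 0.27, adjusted p = 4.0e-11). Lower and below background in haploids on some or all arrays, in no order, were CG12643 (at least 17.1-fold), GNBP3 (at least 3.55-fold) and Shmt (at least 1.83-fold). Also low in haploids were CG17598 (intensity 25.6 ± 8.22 against 427 ± 19.3, 1 of 3 lower arrays above background), AgmNAT (at least 1.01-fold) and Grip (at least 1.67-fold). Beyond these came CG30159 (at least 4.82-fold), Ih (at least 1.35-fold) and CG32485 (at least 2.17-fold). Dorsoventral genes counted 9 higher and 1 lower (10 and 1 adjusted over the list alone, median 0.44, camera adjusted p = 0.0092, adjusted p = 0.22 with an estimated correlation) of 17. Replication genes counted 6 higher and 10 lower (6 and 13 adjusted over the list alone, median -0.36, camera adjusted p = 0.036, adjusted p = 0.22 with an estimated correlation) of 22. Maternal transcripts counted 1 higher and 10 lower (2 and 12 adjusted over the list alone, median -0.55, camera adjusted p = 3.0e-05, adjusted p = 0.11 with an estimated correlation) of 19. Germ cell markers counted 2 higher and 8 lower (2 and 8 adjusted over the list alone, median -0.82, camera adjusted p = 7.9e-04, adjusted p = 0.12 with an estimated correlation) of 12. Heat shock genes counted 1 higher and 4 lower (1 and 4 adjusted over the list alone, median -0.53, camera adjusted p = 0.045, adjusted p = 0.17 with an estimated correlation) of 8. Amnioserosa markers counted 6 higher and 0 lower (7 and 1 adjusted over the list alone, median 0.40, camera adjusted p = 0.029, adjusted p = 0.32 with an estimated correlation) of 12. The gap and terminal list did not pass, with 3 higher and 2 lower (3 and 2 adjusted over the list alone, median 0.21, camera adjusted p = 0.52). The calls numbered 3838, 2044 higher and 1794 lower, or 426 and 760 with at least 2-fold difference. Haploids were higher in 53.3% of them in the main analysis, 6.45% on the deposited scale, 24.1% with median centring, 14.9% with ribosomal protein centring and 17.2% with poly-A centring.

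At the third matched stage, late cycle 15, with its high 18S control, against late cycle 14, the largest difference measured above background on every array, higher in haploids, was that of gammaTub37C (log2 3.64 ± 0.13, adjusted p = 8.4e-15). Higher from a diploid level below background on some or all arrays, in no order, were Cyp28a5 (at least 4.48-fold), Naxe (at least 1.24-fold) and Esp (at least 1.91-fold). In the same set were CG14109 (at least 1.14-fold), the sodium pump subunit nrv2 (at least 1.27-fold) and the growth factor Pvf1 (intensity 293 ± 28.4 against 34.0 ± 11.7, 2 of 3 lower arrays above background). Completing it were CG30460 (at least 3.04-fold), CR17567 (intensity 29.9 ± 8.07 against 5.17 ± 5.73, 1 of 3 higher arrays above background) and CG43064 (at least 3.20-fold). The largest difference the other way measured above background was that of CtsK1 (log2 -3.29 ± 0.15). Lower and below background in haploids on some or all arrays, in no order, were CG12643 (at least 16.4-fold), GNBP3 (at least 1.98-fold) and Prestin (at least 1.38-fold). Lower in the same way were CG4586 (at least 6.90-fold), CG5567 (at least 3.27-fold) and CG9782 (at least 1.30-fold). Completing these were Pp2B-14D (intensity 32.0 ± 15.9 against 256 ± 71.5, 2 of 3 lower arrays above background), CG17598 (intensity 51.9 ± 20.8 against 389 ± 33.0, 2 of 3 lower arrays above background) and Obp56a (at least 3.00-fold). Maternal transcripts were lower in haploids, 0 higher and 15 lower (0 and 15 adjusted over the list alone, median -0.85, camera adjusted p = 9.7e-10) of 19, with twe (log2 -0.84 ± 0.11) lower too. Early zygotic genes counted 3 higher and 11 lower (4 and 11 adjusted over the list alone, median -0.13, camera adjusted p = 0.026, adjusted p = 0.43 with an estimated correlation) of 28. The gap list did not pass, with 1 higher and 4 lower (2 and 4 adjusted over the list alone, median 0.05, camera adjusted p = 0.91). The calls numbered 3058, 1363 higher and 1695 lower, or 300 and 558 with at least 2-fold difference. Haploids were higher in 44.6% of them in the main analysis, 16.0% on the deposited scale, 31.7% with median centring, 28.3% with ribosomal protein centring and 9.58% with poly-A centring.

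Some differences between haploids and diploids held at every matched stage. With at least 2-fold difference in the same direction, 77 probe sets of 60 genes were higher in haploids at all 3 stages, where independence would give 0.462, and 138 of 117 genes were lower, where independence would give 2.49. Of the 77 higher probe sets, 23 were kept on the deposited scale, 57 with median centring and 37 with ribosomal protein centring, and of the 138 lower ones 135, 121 and 126. Cyp28a5, gammaTub37C, CG30460, CG43064 and CG8654 were among the higher genes, and CG12643, GNBP3, CG30159, Pp2B-14D and Sans among the lower genes. This set was chosen after the values were seen.

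The same-age comparison set haploid cycle 14 embryos against diploid early cycle 14 embryos. Gap genes were lower in haploids. Of 15 gap and terminal genes, 0 were higher and 12 lower (0 and 12 adjusted over the list alone, median -0.94, camera adjusted p = 2.0e-09). Transcripts of hkb (log2 -1.21 ± 0.11, adjusted p = 3.1e-08), kni (log2 -1.04 ± 0.12) and hb (log2 -0.85 ± 0.13) were below the diploid level. The early zygotic genes split, with 10 higher and 13 lower (10 and 13 adjusted over the list alone, median -0.11, camera adjusted p = 0.078) of 28. Transcripts of slam (log2 -1.18 ± 0.10, adjusted p = 4.9e-09), Z600 (log2 -1.33 ± 0.09), trbl (log2 -1.22 ± 0.12) and zld (log2 -1.22 ± 0.13) were lower in haploids, while the cellularization gene bnk (log2 0.93 ± 0.12) was higher, a call lost on the deposited scale (log2 0.09) and with poly-A centring (0.19). Of the pair-rule genes, 0 were higher and 4 lower (0 and 6 adjusted over the list alone, median -0.93, camera adjusted p = 3.2e-04, adjusted p = 0.11 with an estimated correlation). Of the dorsoventral genes, 1 was higher and 5 lower (1 and 5 adjusted over the list alone, median -0.20, camera adjusted p = 0.036, adjusted p = 0.32 with an estimated correlation). Of the cellularization genes, 2 were higher and 6 lower (2 and 7 adjusted over the list alone, median -0.40, camera adjusted p = 0.026, adjusted p = 0.25 with an estimated correlation). The transcription regulators counted 0 higher and 9 lower (1 and 10 adjusted over the list alone, median -0.49, camera adjusted p = 1.0e-05, adjusted p = 0.094 with an estimated correlation) of 17. The Bearded and Enhancer of split family was higher, with 8 higher and 0 lower (8 and 0 adjusted over the list alone, median 0.83, camera adjusted p = 6.3e-06, adjusted p = 0.11 with an estimated correlation) of 12. Brd transcripts stood at 1446 ± 183 against 421 ± 89.2 (log2 1.80 ± 0.12, adjusted p = 1.7e-10), close to the 1445 ± 165 of diploid cycle 13. Transcripts of E(spl)m7-HLH (log2 1.47 ± 0.24) were higher too, although the call was lost on the deposited scale (log2 0.61) and with poly-A centring (0.70).

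Above background on every array, the genes highest in haploids of the same age were gammaTub37C (log2 3.95 ± 0.13) and the proneural gene ac (log2 2.89 ± 0.14). Higher from a diploid level below background, in no order, were Cyp28a5 (at least 1.61-fold), CG17568 (at least 2.15-fold), CG7650 (at least 3.94-fold) and CG31174 (intensity 30.9 ± 4.64 against 8.17 ± 6.43, 1 of 3 higher arrays above background). A higher level was also called for Ugt50B3 (at least 1.51-fold), CG30460 (at least 2.77-fold), the autophagy gene Atg12 (at least 2.496-fold) and CG13047 (at least 1.49-fold). All 10 genes with the largest fitted difference the other way were below background in haploids. In no order, these were GNBP3 (at least 3.55-fold), CG12643 (at least 17.1-fold), Zip102B (at least 1.31-fold) and Sans (at least 1.84-fold). A lower level was also called for CG30159 (at least 4.82-fold), salm (at least 1.65-fold) and Ih (at least 1.35-fold). Adding to these were Obp56a (at least 2.44-fold), CG42258 (at least 1.87-fold) and Gmap (at least 1.56-fold). In all 2987 probe sets were called, 1480 higher and 1507 lower in haploids, or 190 and 424 with at least 2-fold difference. Haploids were higher in 49.6% of calls in the main analysis, 0.997% on the deposited scale, 42.4% with median centring, 9.06% with ribosomal protein centring and 1.17% with poly-A centring. The gap and terminal list stayed lower than all genes with quantile scaling, on the deposited scale and with median and ribosomal protein centring.

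The scaling also moved the median of all probe sets. On the deposited scale it was 0.29 in the diploid first step, -0.19 in the second, 0.39 in the haploid first step, -0.49, -0.32 and -0.15 at the 3 matched stages, and -0.75 at the same age. For the differences between the steps of haploids and diploids it was 0.11 and 0.16. Ribosomal protein centring gave -0.28 and -0.11 at the first and second matched stages, -0.24 at the same age and 0.11 for the difference in the first step. Median centring gave -0.11 in the diploid second step, -0.15 in the haploid second step and -0.18 for the difference in the first step. Poly-A centring gave -0.40 in the diploid second step, 0.64 and -0.70 in the haploid steps, -0.56 and -0.25 at the first and last matched stages, -0.65 at the same age, and 0.52 and -0.28 for the differences between steps.

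The level of each diploid change in haploid cycle 14 embryos was then read gene by gene. Among the 452 probe sets that rose at least 2-fold, 61 stood at the diploid cycle 13 level, 93 between the levels, 184 at the early cycle 14 level and 114 in none of these classes. Among the 737 that fell, 32 stood at the cycle 13 level, 48 between, 474 at the early cycle 14 level and 183 in none. The median position was 0.727 ± 0.041 for rises and 1.07 ± 0.089 for falls (SD over n = 3 haploid arrays). The sorting of rises turned with scaling. The median position of rises was 0.340 on the deposited scale, 0.558 with ribosomal protein centring and 0.355 with poly-A centring, and that of falls was 1.674 and 1.590 on the deposited scale and with poly-A centring. Rises at the cycle 13 and the early cycle 14 level numbered 249 and 75 on the deposited scale and 151 and 56 with poly-A centring. By the naming rule, rises at the cycle 13 level included salm, ry, Cyp312a1, croc, CG43163, ASPP, fkh and gbb. In 39 of the 61 both the cycle 13 and the haploid level were below background, these 8 genes among them, so equal levels were not measured for them. For the forkhead gene croc the intensity was 11.1 ± 10.6 in diploid cycle 13, 52.0 ± 11.3 in early cycle 14 and 12.1 ± 8.80 in haploid cycle 14, and for the other forkhead gene fkh it was 14.7 ± 3.3, 55.5 ± 12.5 and 22.1 ± 15.7. Rises already at the early cycle 14 level included net, CG43394, phu, Ac78C, eEF1alpha2, lov, 18w and janB. The adenylate cyclase gene Ac78C had 69.2 ± 21.9, 548 ± 77.5 and 492 ± 76.1 at these stages. Rises between the levels included nub, kmr, Pka-C3, Ptr, rib, link, CG15628 and ckn, and Ptr had 40.98 ± 17.5, 526 ± 36.7 and 204 ± 48.3.

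In 104 of the 474 falls at the early cycle 14 level both that level and the haploid level were below background, among them Opbp, CG8323, CrebB, MTPAP, syd, Pld and CG12945. Measured above it was Gk2, with 738 ± 137, 80.01 ± 10.5 and 52.6 ± 4.95. Falls still at the cycle 13 level in haploids included Naxe, mthl5, CG17568, Naa35, Brd, al, S1P and Atg12. Of the 32 falls in this class, 14 had both the cycle 13 and the haploid level below background. The gap and terminal genes had 11 rises of at least 2-fold with a median position of 0.391. Of these, gt, ems, btd, fkh and croc stood at the cycle 13 level, D, Kr, tll, hkb and kni stood between, and oc stood at the early cycle 14 level. The early zygotic list had 13 such rises with a median of 0.499, of which slam, gt and dpn stood at the cycle 13 level. Maternal transcripts had 7 such falls with a median of 1.20 and replication genes 6 with a median of 1.251. Some sorting depended on scaling. Under quantile scaling, the deposited scale, median, ribosomal protein and poly-A centring and an offset before log2, the same class was kept by 38 of the rises at the cycle 13 level, 33 of the rises at the early cycle 14 level and 99 of the falls at the early cycle 14 level. The median position of falls stayed above that of rises under each of these.

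**Figure D3:**
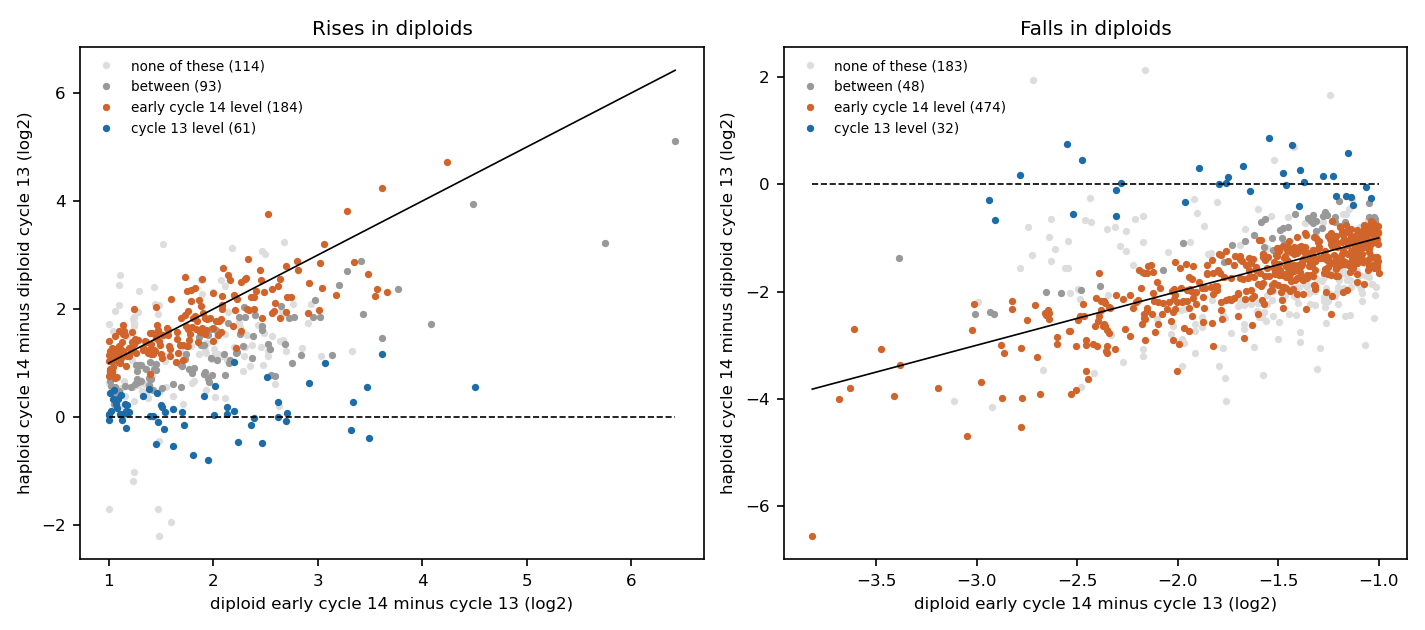
Log2 haploid cycle 14 minus diploid cycle 13 level against the diploid change, with cycle 13 at 0 and early cycle 14 on the diagonal.

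**Figure D4:**
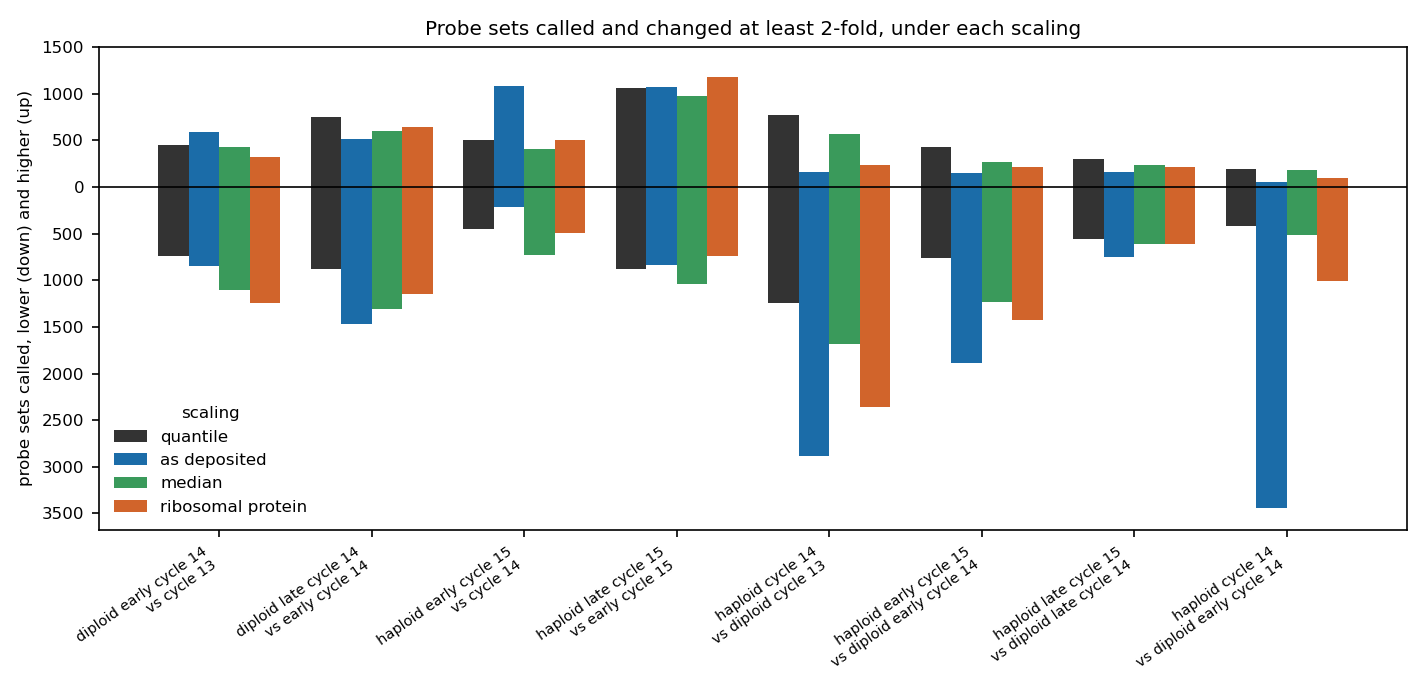
Calls of 2-fold or more, up and down, by comparison and planned scaling.

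The last tests asked whether a step differed in size between haploids and diploids. In the first step 1304 probe sets were called, 574 with a more positive change in haploids and 730 with a more negative one. With at least 2-fold difference the balance was the other way, with 386 more positive and 119 more negative. More positive in haploids were CG7884 (log2 4.74 ± 0.91), Dtwd2 (log2 4.04 ± 0.78) and the Enhancer of split factor E(spl)m5-HLH (log2 3.90 ± 0.69), and more negative were the lysozyme gene LysS (log2 -4.01 ± 1.03), CG14958 (log2 -3.46 ± 0.80) and nub (log2 -3.34 ± 0.30). Each of these genes, and of those named for the second step, had at least 1 group mean below background, so the size of the difference is uncertain. Early zygotic genes had a less positive change in haploids, with 1 higher and 15 lower (1 and 20 adjusted over the list alone, median -0.42, camera adjusted p = 4.4e-10, adjusted p = 0.058 with an estimated correlation) of 28. The same held for dorsoventral genes, 2 higher and 6 lower (2 and 9 adjusted over the list alone, median -0.27, camera adjusted p = 0.0057, adjusted p = 0.2 with an estimated correlation). For cellularization genes there were 1 higher and 5 lower (1 and 6 adjusted over the list alone, median -0.39, camera adjusted p = 0.028, adjusted p = 0.25 with an estimated correlation). For sex determination genes there were 0 higher and 4 lower (0 and 4 adjusted over the list alone, median -0.24, camera adjusted p = 0.015, adjusted p = 0.094 with an estimated correlation). The fall was smaller in haploids for replication genes, 9 higher and 1 lower (9 and 2 adjusted over the list alone, median 0.20, camera adjusted p = 0.0037, adjusted p = 0.12 with an estimated correlation). For heat shock genes there were 2 higher and 1 lower (2 and 1 adjusted over the list alone, median 0.49, camera adjusted p = 0.041, adjusted p = 0.16 with an estimated correlation). Transcription regulators counted 5 higher and 1 lower (6 and 1 adjusted over the list alone, median 0.23, camera adjusted p = 0.004, adjusted p = 0.22 with an estimated correlation). The share of calls with a more positive change was 44.0% in the main analysis, 86.4% on the deposited scale, 38.3% with median centring, 80.6% with ribosomal protein centring and 99.04% with poly-A centring.

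In the second step 2109 probe sets were called, 952 with a more positive and 1157 with a more negative change in haploids. Here too the balance turned at 2-fold, to 521 more positive and 287 more negative. More positive were Rilpl (log2 5.09 ± 1.10), MFS10 (log2 4.54 ± 0.97) and px (log2 4.41 ± 0.50), and more negative were CG9782 (log2 -3.41 ± 1.08), the homeobox gene al (log2 -3.34 ± 0.87) and CG9109 (log2 -3.29 ± 0.86). Early zygotic genes counted 1 higher and 14 lower (1 and 17 adjusted over the list alone, median -0.41, camera adjusted p = 6.3e-06, adjusted p = 0.13 with an estimated correlation) of 28. Dorsoventral genes counted 0 higher and 5 lower (1 and 7 adjusted over the list alone, median -0.44, camera adjusted p = 0.0078, adjusted p = 0.22 with an estimated correlation) of 17. Amnioserosa markers counted 0 higher and 5 lower (0 and 6 adjusted over the list alone, median -0.62, camera adjusted p = 0.025, adjusted p = 0.3 with an estimated correlation) of 12. Replication genes counted 7 higher and 1 lower (9 and 3 adjusted over the list alone, median 0.44, camera adjusted p = 0.0092, adjusted p = 0.13 with an estimated correlation) of 22. Germ cell markers counted 5 higher and 1 lower (6 and 2 adjusted over the list alone, median 0.39, camera adjusted p = 0.025, adjusted p = 0.27 with an estimated correlation) of 12. The share with a more positive change was 45.1% in the main analysis, 87.1% on the deposited scale, 68.7% with median centring, 75.7% with ribosomal protein centring and 55.5% with poly-A centring.

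**Figure D5:**
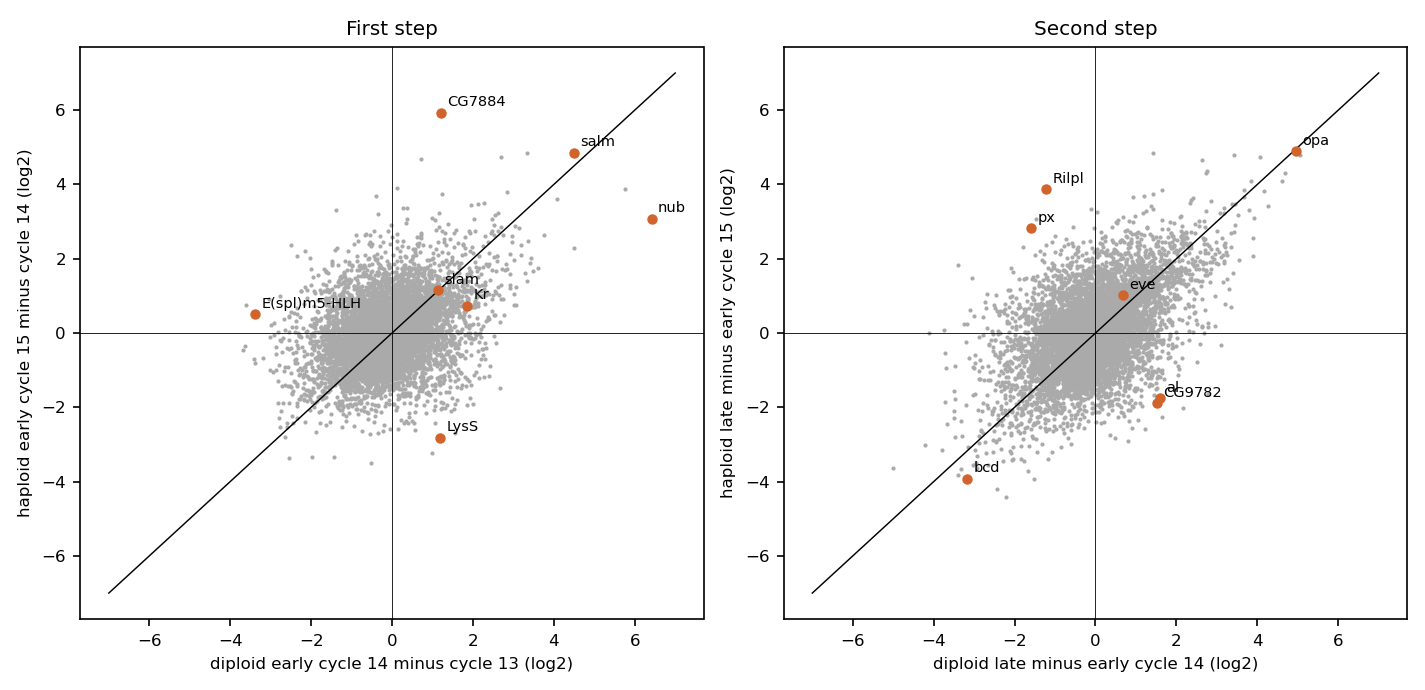
Log2 change of each gene in haploids against the matched change in diploids for the first and second step.

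Several lists passed camera in no contrast. The 18 cell cycle regulators had 5 higher and 7 lower (6 and 8 adjusted over the list alone, median -0.16, camera adjusted p = 0.51) in the diploid first step, and in the second, besides those named above, CycD (log2 -0.87 ± 0.08) and fzr (log2 -0.67 ± 0.14) fell, while fzr rose in the haploid second step (log2 0.82 ± 0.14; 0.15 and not called with poly-A centring). The 14 DNA damage and cell death genes had 5 higher and 4 lower (6 and 4 adjusted over the list alone, median -0.38, camera adjusted p = 0.99) in the diploid first step. The death ligand gene egr rose (log2 2.14 ± 0.12). Of 2 measured histone genes, BigH1 fell at every step and His2Av was called in none. The diploid first step had 0 higher and 1 lower (0 and 1 adjusted over the list alone, median -0.47, camera adjusted p = 0.35). The 41 ribosomal protein genes had 3 higher and 0 lower (1 and 0 adjusted over the list alone, median -0.10, camera adjusted p = 0.89). The 8 segment polarity and Hox genes had 2 higher and 0 lower (2 and 0 adjusted over the list alone, median 0.57, camera adjusted p = 0.48). Between early and late cycle 14, nkd (at least 5.43-fold) and ptc (intensity 110 ± 4.54 against 28.7 ± 4.65, 1 of 3 lower arrays above background) rose in the segment polarity list. Among the 9 later nervous system markers 2 were higher and 0 lower (1 and 0 adjusted over the list alone, median -0.29, camera adjusted p = 0.86) in the first step. Transcripts of elav (intensity 254 ± 17.0 against 28 ± 6.58, 1 of 3 lower arrays above background) rose in the second. Among 5 muscle and blood markers 1 was higher and 0 lower (1 and 0 adjusted over the list alone, median 0.48, camera adjusted p = 0.88), namely SPARC. The 67 epidermis and cuticle markers had 4 higher and 3 lower (2 and 2 adjusted over the list alone, median -0.03, camera adjusted p = 0.78). The cuticle regulator grh (log2 2.71 ± 0.24) rose later. The 13 mother tissue markers had 1 higher and 0 lower (1 and 0 adjusted over the list alone, median 0.23, camera adjusted p = 0.67), the cadherin gene Cad74A alone. The 6 immune response genes had 0 calls in every contrast, where 1 of them had an unadjusted p below 0.05 in the haploid first step and none elsewhere. Their diploid first step had 0 higher and 0 lower (0 and 0 adjusted over the list alone, median 0.00, camera adjusted p = 0.9).

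For X-linked genes the question was whether a haploid, with 1 X chromosome per set of autosomes, differs from diploid embryos that mix XX and XY. In none of the 4 comparisons of haploids with diploids did camera separate the 1604 X-linked genes from the 8373 autosomal genes at an adjusted p below 0.05 with the preset correlation, and the same held among genes that rise in diploids. The lowest value, 0.12, came from the same-age comparison, where the median of X-linked genes lay 0.13 log2 units under that of autosomal genes (unadjusted p = 0.015). That comparison passed with an estimated correlation (adjusted p = 0.0356) and with the stricter filter (0.0377). Among genes that rise in diploids the sign turned on the deposited scale at the first matched stage (-0.097 to 0.055) and the same age (-0.069 to 0.123). Of the 8 tests, 1 had an unadjusted p below 0.05.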

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

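The tests of scaling, of background, of X linkage, of selection and of a slower time course, and the splits with the shared difference removed, were chosen only after the results were seen.

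A test of the difference between haploids and diploids set apart 1304 probe sets in the first step and 2109 in the second. In the first step the change differed by log2 4.74 for CG7884, 4.04 for Dtwd2 and 3.90 for E(spl)m5-HLH, more positive in haploids. It differed by -4.01 for LysS, -3.46 for CG14958 and -3.34 for nub, more negative in haploids. In the second step it differed by 5.09 for Rilpl, 4.54 for MFS10 and 4.41 for px, and by -3.41 for CG9782, -3.34 for al and -3.29 for CG9109. Each of these 12 genes had at least 1 group mean below background. The same test on gene lists gave a difference in the first step of -0.421 for early zygotic genes, -0.392 for cellularization genes, -0.273 for dorsoventral genes, -0.243 for sex determination genes, 0.489 for heat shock genes, 0.232 for transcription regulators and 0.203 for replication genes. For the second step it gave -0.618 for amnioserosa and yolk markers, -0.440 for dorsoventral genes, -0.408 for early zygotic genes, 0.442 for replication genes and 0.389 for germ cell markers. With an estimated correlation none of these list differences passed, with adjusted p of 0.0579 to 0.251 in the first step and 0.132 to 0.30 in the second.

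Of 100 splits of the 12 samples within stages, 5 gave as many calls as the first step's 1304, the highest 5604, and 2 gave as many as the second step's 2109, the highest 4176. The 5 and the 2 include the real split. The splits with the highest counts exchange whole groups at 1 stage, so they measure the large difference between haploids and diploids itself. These counts thus cannot decide on chance in either step. With that shared difference removed, 1 of 100 splits, the real one, gave as many calls in each step, and the highest other gave 2 and 344. For gene lists, 2 of 100 splits of the 18 samples gave at least the real 68 list and contrast pairs. The highest, 78, leaves chance open for single pairs.

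The 6 samples of a comparison of 2 groups make 10 splits, too few for a share under 0.05. Only 1 split, the real one, gave as many calls in each comparison. Real and highest other counts were 3977 and 2, 4082 and 1, 2954 and 2, and 4209 and 0 for the 4 steps in the order described, 5192 and 4, 3838 and 1, and 3058 and 1 for the 3 matched stages, and 2987 and 1 at the same age. For rises at the cycle 13 level they were 61 and 0.

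Control probe sets for fly genes, which the comparisons did not use, differed between groups. The probe set for the middle of 18S ribosomal RNA averaged 986.6 in haploid late cycle 15 against at most 395.7 in the other groups. The GAPDH control probe sets averaged 965.2 at the 3' end, 360.7 at the 5' end and 729.1 in the middle in diploid cycle 13, against at most 151.6, 105.3 and 170.5 in the other groups. Actin and eIF-4a control probe sets differed by at most 1.52-fold between groups, which argues against RNA handling in diploid cycle 13. The role of RNA handling was not tested in diploid cycle 13 or in haploid late cycle 15.

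The first pattern weighed was that more probe sets rose than fell between diploid cycle 13 and early cycle 14. Probe sets near background did not account for it, since 61.8% of the calls above background were higher. The choice of scaling may account for it, since the share fell to 22.97% with ribosomal protein centring. No biological explanation was tested, and a true excess of small rises stays open.

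The second pattern was the set of differences between haploids and diploids that held at all 3 matched stages. Under other centring at least 121 of 138 lower probe sets were kept. Of 77 higher ones, ribosomal protein centring kept 37 and the deposited scale 23. Both shift haploids down, which favours lower ones, so scaling stays open for both. Of the lower probe sets with a known chromosome 26.1% were X-linked against 16.4% of those tested (Fisher p = 0.00838; 26.7% against 16.1% with each gene counted once, p = 0.00317), which variants linked to the X chromosome of the mutant mothers could give, although 88 probe sets lay elsewhere, and for the higher probe sets the test left this open (p = 0.293, or 0.213 by genes). Other probe sets of the same genes had a median difference of -0.508 ± 0.173 (SE, 19 probe sets) for lower and 0.596 ± 0.325 (12 probe sets) for higher genes, too near the bound of 0.5 set for them to tell sequence variants under single probe sets from changed transcripts. Genotype of the mothers, ploidy and age in minutes differ together between the groups, so a biological difference stays open and untested.

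The third pattern was that falls had reached the early cycle 14 level in haploid cycle 14 embryos while rises lagged behind it. Selection did not explain it, since the gap in median position was at least 0.299 with genes selected on other replicates. The other scalings mostly lower haploids, which widens the gap (at least 0.454), so scaling stays open. Dim probe sets did not explain it, with a gap of 0.400 in the brightest 25%. A slower time course would hold back falls, whose median position was at least 1.07 over the planned scalings and 0.982 with a 4-fold minimum. No earlier haploid level was measured, so this stays open. The gap is limited to large changes, because with no fold minimum the medians were 1.073 for rises and 1.065 for falls. No biological explanation was tested, since DNA content, maternal genotype and possibly true age change together.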

How the results depend on the processing

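Poly-A centring and the filter that counts probe sets above background only were chosen after seeing the data, as were the genes compared across settings here. All 225 pairs of a named gene and a comparison kept their direction in every setting that gave them a value. On the deposited scale calls at the same age were lost for bnk (log2 0.09, adjusted p = 0.672), E(spl)m7-HLH (0.61, 0.0934) and CG31174 (1.86, 0.0912), and with ribosomal protein centring for CG31174 (2.37, 0.0788). Poly-A centring ended the same 3 calls (0.19, 0.70 and 1.96, adjusted p = 0.555, 0.0931 and 0.101), that of fzr in the haploid second step (0.15, 0.627) and that of MTPAP in the diploid first step (-3.10, 0.0508). Calls at an adjusted p near 0.05 also ended under other settings. That of CG31174 ended with no filter (0.0518), no intensity trend (0.0707), array weights (0.0725) and the compared groups alone (0.0502), and that of CG5805 in the haploid first step with the compared groups alone (0.0518). That of CG9782 in the second step ended with no filter (0.0501) and no trend (0.0787), and that of nrv2 at the last matched stage with no trend (0.0748). With the stricter filter 6 pairs were not tested. Under background, direction and fold are not measured, and the haploid cycle 14 arrays had the smallest share of probe sets above it. For each changed count or value below the cause was not tested, except that a fold minimum changes how many genes are sorted.

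Counts of calls moved by over 1.5 times in these cases. On the deposited scale the same-age comparison gave 6923 against 2987 and the difference in the first step 743 against 1304. Ribosomal protein centring gave 2603 against 3977 for the diploid first step. Poly-A centring gave 1733 for that step, 4593 against 2954 for the haploid first step, 1936 against 3838 and 1775 against 3058 for the matched stages after the first, 4629 for the same age, and 650 against 2109 for the difference in the second step.

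Sorting by the haploid cycle 14 level moved as well. Rises at the cycle 13 level, 61 in the main analysis, were 249 on the deposited scale, 151 with poly-A centring, 347 with no fold minimum and 23 with a 4-fold minimum. Rises at the early cycle 14 level, 184, were 75 on the deposited scale, 97 with ribosomal protein centring, 56 with poly-A centring, 1120 with no minimum and 61 with the 4-fold minimum. Falls at the early cycle 14 level, 474, were 212 on the deposited scale, 733 with median centring, 735 with ribosomal protein centring, 865 with no minimum and 111 with the 4-fold minimum. The median position of rises, 0.727, was 0.340 on the deposited scale, 0.558 with ribosomal protein centring, 0.355 with poly-A centring, 1.073 with no minimum, 0.680 with the 4-fold minimum, and 0.706 to 0.788 when leaving out 1 array. That of falls, 1.071, was 1.674, 1.312 and 1.590 under these 3 scalings, 0.982 with the 4-fold minimum and 1.162 with genes selected on replicates 2 and 3 and measured on replicate 1.

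Of 68 pairs of list and contrast that passed, 60 also passed on the deposited scale, 56 with median centring, 62 with ribosomal protein centring and 58 with the stricter filter. An estimated correlation left 13, and the rotation test fry passed 143. For X-linked genes that rise in diploids, the difference turned from -0.097 to 0.055 at the first matched stage and from -0.069 to 0.123 at the same age on the deposited scale. The same-age difference over all genes passed with the stricter filter (-0.156, adjusted p = 0.0377) and with an estimated correlation (-0.129, adjusted p = 0.0356), and its adjusted p ran up to 0.29 over the settings.

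Leaving out 1 array gave 3402 to 3685 calls for the diploid first step and 2198 to 2892 for the same age. It ended the call of CG31174 at the same age without any haploid cycle 14 replicate (adjusted p = 0.0779, 0.0926 and 0.10) and without diploid early cycle 14 replicate 1 (0.289). In the diploid first step it ended that of CrebB without early cycle 14 replicate 3 (0.0602) and that of MTPAP without early cycle 14 replicate 1 (0.141) or 2 (0.0605). That of nrv2 at the last matched stage ended without any of haploid late cycle 15 replicates 1 to 3 (0.0688, 0.0730 and 0.0575) or diploid late cycle 14 replicates 1 and 2 (0.0948 and 0.128). That of CG9782 in the second step ended without haploid early cycle 15 replicate 3 (0.0930), haploid late cycle 15 replicates 2 or 3 (0.0616), diploid early cycle 14 replicate 2 (0.121) or diploid late cycle 14 replicates 2 or 3 (0.0702 and 0.0715).

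The replicate numbers do not pair the samples, since deviations of arrays with the same number correlated at -0.023 to 0.033. With the number as a block the diploid first step had 4003 calls and the same-age comparison 3054.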

Other observations

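The test of template dose was written before its result was seen, and the genes described first were chosen after their values were seen.

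These genes were picked one by one, and no test of a gene group stands behind them. Among the genes lower in haploids at all 3 matched stages, Gapdh1 stood at 652 ± 138 in haploid cycle 14 against 2627 ± 252 in diploid cycle 13 (SD, n = 3), and at 128 ± 21.6 against 349 ± 23.1 at the last stage. GAPDH controls also stood apart in diploid cycle 13, while actin and eIF-4a ones varied at most 1.52-fold after scaling. RNA handling was not tested. Idh stood at 795 ± 91.3 against 2637 ± 301 at the first stage and 155 ± 16.5 against 367 ± 13.4 at the last, and the glycogen phosphorylase gene Glyp at 333 ± 63.5 against 1559 ± 48.7 and 174 ± 52.2 against 472 ± 28.9. The poly-A polymerase gene wisp stood at 1338 ± 264 against 4182 ± 228 and 324 ± 43.6 against 891 ± 146, and otu at 764 ± 197 against 2794 ± 630 and 87.3 ± 3.32 against 286 ± 28.4. Each of these 5 genes also stood lower at the last than at the first stage within diploids and within haploids.

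Among the genes higher in haploids at all 3 matched stages, the neuronal gene elav stood at 829 ± 55.0 in haploid late cycle 15 against 254 ± 17.0 in diploid late cycle 14, and the segment polarity gene nkd at 596 ± 82.6 against 175 ± 24.9. The Hedgehog effector ci stood at 2284 ± 191 against 957 ± 81.9, and the cell surface gene trn at 664 ± 92.8 against 261 ± 22.9. From the sex determination list, Sxl stood at 5229 ± 335 against 2771 ± 288, while msl-2 stood at 262 ± 33.7 against 325 ± 19.3 and was not called (adjusted p = 0.173).

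A hypothesis tested was that genes transcribed in this period are lower in haploid than in diploid embryos of the same age because each nucleus has 1 template copy in place of 2, which would put their median near -1 in log2. The 138 genes that rose at least 4-fold from diploid cycle 13 to late cycle 14 had a median of -0.358 relative to all genes, with quartiles of -0.793 and 0.002. Under the other planned scalings the median was -0.609, -0.616 and -0.601. These values lie short of the full effect of template dose, and the scaling decides on which side of the bound of -0.5 they fall, so the test left the hypothesis open. Against diploid embryos 1 cycle younger the 138 genes were higher in haploids, by 1.23, 0.809 and 0.319 at the 3 matched stages.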
